A study of Mus musculus with 12 samples.

How the data were processed

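RNA of isolated left-ventricular cardiomyocytes was labelled with biotin and hybridised to Illumina bead arrays, per the labels' protocols. The samples were placed in 4 groups of 3 arrays by their titles: sham or TAC surgery, each with the scrambled hairpin (shControl) or the hairpin against Uhrf1 (shUhrf1). The deposited non-normalized table gives an intensity per probe and array on a linear scale, with no background subtraction visible in the values, and, per the file headers, a detection p-value per probe and array. The deposited detection p-values fall on a grid of 936 steps, the number of negative control probes this implies. The authors' value table holds log2-like values made with lumi, per the submitters' processing notes, whose version and settings are not given in the sources used here. Every array of that table had the same median of 7.50, a lowest value of 7.36 and a highest of 15.07, and each column ranked the probes as that array's intensity did (Spearman correlation 1). The table is therefore normalized between arrays by quantiles and compressed at low intensity, and it was used as an alternative. The scanner and its software are not given in the sources used here.

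Probes were named through GEO's platform annotation. Of the 45281 probes 34885 had 1 symbol, 18 had several and were not named, and 10378 are unnamed here. No coordinates are given, because no genome was used here.

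The intensities were background-corrected with limma's neqc, which estimates the background from the detection p-values, adds an offset of 16 and quantile-normalizes the log2 values. Probes with a detection p under 0.01 on at least 3 of the 12 arrays were kept, which left 15118 probes and 8746 named genes. A gene was represented by its probe with the highest mean over the arrays. limma 3.58.1 in R 4.3.3 was fitted to all 12 arrays with 1 mean per group, so that the groups shared 1 estimate of the spread, and moderated with eBayes. A gene changed when its Benjamini-Hochberg adjusted p over all probes tested was under 0.05. The 5 comparisons were TAC against sham in shControl and in shUhrf1, shUhrf1 against shControl in sham and in TAC, and the difference between the TAC responses (the interaction). Values are log2 differences ± SE unless an SD is named. Where a gene was undetected on every array of a group, the fold is given as at least N, from the mean of the brighter group over the mean of, per array, the higher of the lowest detected signal and the gene's own signal. No fold is given where both groups were undetected. The number of arrays limits the precision.

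Before the data were examined, 27 lists of genes were fixed: matrix, hypertrophy and fetal genes, adult contraction, fatty acid oxidation, oxidative phosphorylation, cell cycle, immune and stress responses, DNA methylation and its targets, and markers of other heart and blood cells. Lists with enough measured members, 23 of them, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Of these 10, 12, 5, 7 and 7 passed in the 5 comparisons in the order above, and with a correlation estimated from the 12 arrays 0 passed in each. A list is described by the median log2 difference of its members, with an interval of 95% from 2000 bootstrap draws over genes, and members are also counted when adjusted over the list alone. Genes are not independent replicates. The hypertrophy list shares 4 measured genes with the atrial or smooth muscle lists, and Dcn stands in both the imprinted and the fibroblast list. Of the 12 endothelial markers 11 were detected on at least 1 sham shControl array, so they are not absent from the control preparations.

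The genes named in the text follow a rule of the same date: Uhrf1, the preset genes Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Dnmt1, Dnmt3a and Col1a1, and per comparison the 10 genes with the largest rise and the 10 with the largest fall among those that passed and whose 3 arrays of one group all lay above the 3 of the other. Up to 4 members of a described list with the smallest p are added, and where fewer than 6 genes pass, the 6 with the smallest p. Pcdh12, Icam2, Prc1 and the histone genes fall under this rule. ND6 in sham cells, Mxi1 and Lmod2 after TAC, and Hspa5, Sdhd and Atp5a1 were named after their values were seen.

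The slope of the TAC responses ran through the origin. It was compared with arrangements of the shRNA labels exchanged within each surgery, of which 100 were fitted. Genes changed in opposite directions were set beside the number independent lists give and beside 100 simulated sets of unchanged groups that share the TAC shControl arrays. The fits were tested on simulated data with the real probes' means and spreads and noise drawn independently for each probe. Of 335 probes changed 2-fold per comparison, over 5 simulations, 76.7% were recovered for TAC in shControl, 79.1% for TAC in shUhrf1, 78.5% for shUhrf1 in sham, 83.3% for shUhrf1 in TAC and 33.7% for the interaction. Each simulation tested 15118 probes, and 4.67% to 6.40% of calls were false. Genes are correlated on the real arrays, so these shares need not carry over to them. For the interaction 96.4% of 4-fold changes were recovered.

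Alternatives were quantile normalization without background correction, scaling each array by its median, the authors' value table, no filter on dim probes, probes detected on all 12 arrays, fits of the 2 groups compared alone, an intensity trend with a robust prior, array weights, the replicate number as a block, a fold of at least 1.5, the mean of a gene's probes, an estimated correlation, and leaving out each array in turn. An endothelial score as a covariate and scaling to the median of the probes detected on all 12 arrays were added after the data were seen. Interaction medians over list members detected in every group were also computed then. Genes silent in sham cells drop out of them by construction, so they do not decide the size of an interaction.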

Results

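Gene expression was measured on Illumina mouse bead arrays in cardiomyocytes isolated from the left ventricle of male mice. Pups had received an adeno-associated virus of serotype 9, which infects heart muscle, that carried either a scrambled short hairpin RNA (shControl) or a hairpin against Uhrf1 (shUhrf1). As adults they had sham surgery or transverse aortic constriction (TAC), a narrowing of the aorta that overloads the left ventricle with pressure, and cells were collected at 1 week. The 4 groups held 3 arrays each. The series describes 4 samples run in triplicate and does not say whether the 3 arrays of a group came from separate animals, so p-values measure only the spread between these arrays, which may be technical.

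Between 12309 and 14908 of the 45281 probes were detected per array. The mean number of detected probes was 12720 ± 360 in sham shControl, 13912 ± 590 in TAC shControl, 13362 ± 374 in sham shUhrf1 and 14655 ± 236 in TAC shUhrf1 (SD, n = 3 arrays). shUhrf1 arrays thus had 641.7 more detected probes than shControl arrays after sham surgery and 742.7 more after TAC. Arrays of one group correlated across probes with r of 0.980 to 0.987. The first principal component held 42.3% of the variance and parted TAC from sham arrays. The second held 15.6% and parted all shControl arrays (9.99 to 21.67) from all shUhrf1 arrays (-35.38 to -5.25). Endothelial markers varied within a group as well: their mean deviation was -1.25 on sham shUhrf1 array 2 against 0.15 and 0.20 on the other 2 arrays of that group (log2). That array was also the lowest of its group for macrophage (-1.49), fibroblast (-1.41), interferon (-1.17) and inflammation genes (-0.90).

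Uhrf1, which encodes a protein that binds hemimethylated DNA and brings the maintenance methyltransferase Dnmt1 to replicated DNA, was checked first because it is the target of the hairpin. It was detected on all 3 TAC shControl arrays, on 2 of 3 TAC shUhrf1 arrays and on no sham array. Its log2 intensity was 4.88 ± 0.11 in sham shControl, 6.71 ± 0.51 in TAC shControl, 4.54 ± 0.18 in sham shUhrf1 and 5.36 ± 0.69 in TAC shUhrf1 (SD, n = 3). With TAC, Uhrf1 rose at least 2.56-fold in shControl cells (adjusted p = 0.00205). After TAC it was 2.56-fold lower in shUhrf1 than in shControl cells, a log2 difference of -1.35 ± 0.30 (SE, adjusted p = 0.0355). The exact two-sided permutation test of these 3 against 3 arrays gave p = 0.1, the smallest it can give.

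The TAC response of Uhrf1 in shUhrf1 cells, at least 1.1-fold, did not pass (adjusted p = 0.136). In sham cells both groups lay below background, so the knockdown was not measurable there, and neither a fold in sham nor a difference between the TAC responses is given for Uhrf1. The other Uhrf1 probe was detected on no array. The adjusted p of the TAC difference lay above 0.05 without sham shControl array 3 (0.0514), TAC shControl array 2 (0.138) or 3 (0.118), or TAC shUhrf1 array 1 (0.0725) or 2 (0.0979), and it was 0.0509 in the authors' value table, where Uhrf1 differed by -0.33. It was 0.112 with no filter on dim probes and 0.0676 with only the 2 groups compared. The size depends on the background correction: with quantile normalization and no background correction Uhrf1 differed by -0.60 (adjusted p = 0.0300). With the endothelial score of each array as a covariate, chosen after the data were seen, it differed by -0.81 (adjusted p = 0.521).

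**Figure D1:**
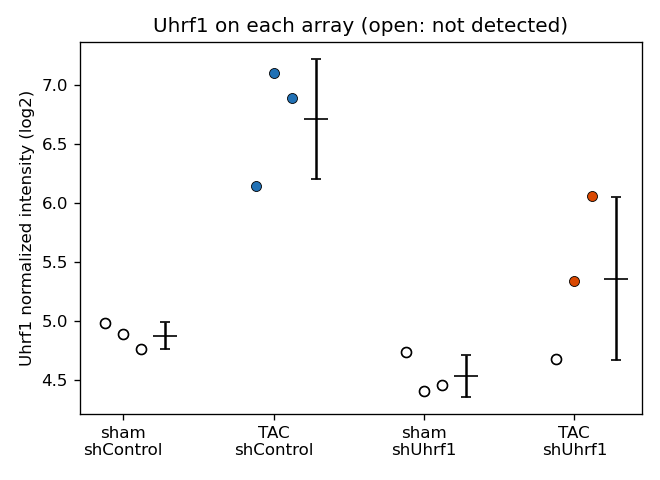
Log2 intensity of Uhrf1 on each array in the 4 groups, with filled points for arrays on which the probe was detected, open points for arrays on which it was not, and black bars for the mean ± SD of 3 arrays. The 3 TAC shControl arrays average 6.71, the 3 TAC shUhrf1 arrays 5.36, and no sham array passed the detection limit.

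The response of the shControl preparations to pressure overload was read from TAC against sham. Markers of fibroblasts, endothelial cells and macrophages rose in it too. A larger share of such cells cannot be told apart here from a change within cardiomyocytes, also for the matrix, cell cycle and immune genes below. Genes of the extracellular matrix showed the highest list median: 21 of 22 measured members rose, with a median log2 fold change of 2.60 (2.26 with genes below background in sham set at their bound). Col1a1, a chain of type I collagen, rose at least 8.54-fold, and Col8a1, a type VIII collagen chain, rose by 3.88 ± 0.37 on the log2 scale (SE, adjusted p = 8.92e-05). Timp1, an inhibitor of matrix metalloproteinases, rose by 2.92 ± 0.28, and Fstl1, a secreted glycoprotein, by 2.84 ± 0.28. Fibroblast markers rose with them, 10 of 12 (median 1.73), led by Mfap5, a microfibril protein, at 3.63 ± 0.33 and by Col6a2 at least 3.50-fold. The list test gave adjusted p = 4.99e-19 for the matrix and 1.41e-08 for fibroblast markers. Neither call held with an estimated correlation (adjusted p = 0.156 and 0.262 with an estimated correlation).

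Hypertrophy genes rose as well: 10 of the 16 measured members of the hypertrophic and fetal list passed (median 1.00, adjusted p = 3.17e-07, and 0.156 with an estimated correlation). Nppa and Nppb, the natriuretic peptides, rose by 1.98 ± 0.29 and 1.06 ± 0.20. Myh7, the beta myosin heavy chain, rose by 2.37 ± 0.52 and Acta1, skeletal alpha actin, by 1.71 ± 0.26. Fhl1, a LIM protein of the sarcomere, rose by 1.35 ± 0.14, Mybpc2 by 2.16 ± 0.23 and Xirp2 by 1.40 ± 0.18. Myh6, the alpha myosin heavy chain (-0.13 ± 0.13), Atp2a2, the calcium pump of the sarcoplasmic reticulum (0.12 ± 0.12), and Dnmt1 (0.18 ± 0.20) did not pass. Of 26 measured fatty acid oxidation genes 6 fell and none rose (median -0.31, adjusted p = 0.000304, and 0.388 with an estimated correlation). Slc27a1, a fatty acid transporter, fell by 1.03 ± 0.24, and Ppara, the nuclear receptor that drives fatty acid catabolism, by 0.81 ± 0.19.

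Cell cycle genes rose in shControl cells after TAC: 11 of 16 measured members passed (median 1.5, 0.72 with genes below background in sham at their bound, adjusted p = 2.38e-09, and 0.156 with an estimated correlation). Only 6 of the 16 were detected on a sham shControl array. Cdc20, an activator of the anaphase-promoting complex, rose at least 2.47-fold, the replication helicase subunit Mcm5 at least 3.09-fold, the topoisomerase Top2a at least 1.62-fold and the spindle protein Nusap1 at least 1.75-fold. Endothelial markers moved in the same direction, with 10 of 12 higher (median 1.60, adjusted p = 3.65e-07, and 0.319 with an estimated correlation). Among them the tight junction protein Cldn5 rose by 2.42 ± 0.25, Cdh5, the vascular cadherin, by 1.88 ± 0.32 and Egfl7 by 2.13 ± 0.39.

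Immune lists rose in the same comparison. Interferon response genes rose in 9 of 16 cases (median 1.04, adjusted p = 2.55e-06, and 0.319 with an estimated correlation), with Rsad2 at 1.98 ± 0.37 and Oasl2 at 1.80 ± 0.38, both antiviral effectors. Inflammation genes rose in 6 of 17 cases (median 0.95, 0.60 with bounds, adjusted p = 5.64e-05, and 0.319 with an estimated correlation), among them Socs3, a feedback inhibitor of cytokine signalling, at 1.44 ± 0.25 and Il1b at 1.62 ± 0.36. Macrophage markers rose in 4 of 14 cases (median 0.77, adjusted p = 6.15e-05, and 0.388 with an estimated correlation), led by Lgals3 at 2.12 ± 0.35 and Adgre1 at 1.35 ± 0.28. Of the 9 measured imprinted genes 3 rose (median 0.65, adjusted p = 0.0216, and 0.319 with an estimated correlation): Mest at least 1.44-fold, Ndn by 0.90 ± 0.23, and Dcn, also a fibroblast marker, by 1.43 ± 0.39.

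The 10 genes with the largest rise in shControl were Col8a1, Col1a1, Mfap5, Prc1, Col16a1, Emp1, Lox, Meox1, Mmp14 and Col5a1. Prc1, a cytokinesis protein, rose at least 7.25-fold, the homeobox factor Meox1 at least 7.37-fold, Col16a1 at least 6.69-fold and the collagen cross-linking enzyme Lox at least 4.61-fold. The largest fall was that of Ano10, of the anoctamin family, at -2.47 ± 0.28. It was followed by Phkg1, the catalytic subunit of muscle phosphorylase kinase, at -2.38 ± 0.28, and Kcnv2, a potassium channel subunit, at -1.94 ± 0.27, with Tbc1d10c, Ttll1, Dnaaf3, Gzmm and Cep128 between -1.73 and -1.48 and Pigh at least 2.37-fold lower.

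In all, 1654 of 8746 genes changed with TAC in shControl, 1001 higher and 653 lower, and 526 of the first and 65 of the second changed at least 2-fold. With each array scaled by its median in place of quantile normalization, 1200 were higher and 72 lower. That scaling moved the median of all genes to 0.19. The count was 875 without TAC shControl array 3 and 991 without sham shControl array 3. It turned no list named above, but the adult contractile list, with a median of 0.02 and no call (adjusted p = 0.907), came to -0.072 and passed (-0.35 with scaling to the median of detected probes). With the endothelial score of each array as a covariate, chosen after the data were seen, 7 genes changed, and the macrophage and imprinted medians turned to -0.35 and -0.083.

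The same response in shUhrf1 cells was again led by the extracellular matrix, where 16 of 22 measured genes rose (median 2.24, adjusted p = 1.49e-20, and 0.155 with an estimated correlation). Timp1 rose by 3.07 ± 0.28, Col3a1 by 3.25 ± 0.33, Col1a1 by 2.69 ± 0.28 and Lox at least 4.72-fold. Hypertrophy genes rose in 8 of 16 cases (median 0.88, adjusted p = 1.56e-08, and 0.155 with an estimated correlation), with Nppa at 1.63 ± 0.29, Nppb at 1.09 ± 0.20, Myh7 at 2.59 ± 0.52 and Acta1 at 1.81 ± 0.26. Myh6, Atp2a2 and Dnmt1 did not pass here either (-0.24, -0.01 and 0.41). Macrophage markers rose in 7 of 14 cases (median 1.06, adjusted p = 3.63e-09, and 0.279 with an estimated correlation), with Lgals3 at 2.68 ± 0.35 and the endotoxin co-receptor Cd14 at 1.87 ± 0.32. Inflammation genes rose in 5 of 17 cases (median 1.00, adjusted p = 3.99e-08, and 0.225 with an estimated correlation), among them Il1b at 2.47 ± 0.36 and the neutrophil chemokine Cxcl2 at 2.38 ± 0.44. Serpina3n, an acute-phase protease inhibitor of the same list, had the largest rise of the genes that passed at 3.73 ± 0.57. Sham shUhrf1 array 2, part of the baseline here, had a low macrophage score, -1.49 against -0.29 and -0.35 on arrays 1 and 3. Its inflammation score was -0.90 against -0.28 and -0.36, so the size of both list rises depends in part on that array.

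The cell cycle and endothelial lists had medians of 1.5 and 1.60 with TAC in shControl. In shUhrf1, of 16 cell cycle genes Mcm6 alone rose, at least 1.79-fold (median of the list 0.36, adjusted p = 0.0229, and 0.472 with an estimated correlation). With genes below background at their bound the cell cycle medians were 0.72 in shControl and 0.25 in shUhrf1. The shUhrf1 median of 0.36 came to -0.015 with scaling to the median of detected probes, chosen after the data were seen. The endothelial list did not pass (median 0.08, adjusted p = 0.932, and median -0.44 without sham shUhrf1 array 2), and of its 12 members Cldn5 alone rose, by 0.97 ± 0.25. Interferon genes had a median of 0.59 with Ifi27l2a alone passing, at 1.80 ± 0.47 (adjusted p of the list = 0.0101, and 0.492 with an estimated correlation). Fibroblast markers rose in 4 of 12 cases (median 0.86, adjusted p = 3.17e-05, and 0.33 with an estimated correlation), and oxidative stress genes in 4 of 17, among them the metallothionein Mt1 at 0.87 ± 0.18 and the secreted peroxidase Gpx3 at 1.58 ± 0.36 (median 0.15, adjusted p = 0.0372, and 0.225 with an estimated correlation). The interferon and fibroblast rises depend in part on sham shUhrf1 array 2. Its interferon score was -1.17 against 0.07 and -0.38 on arrays 1 and 3, and its fibroblast score -1.41 against -0.24 on each.

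The lists of fatty acid oxidation, oxidative phosphorylation, contraction and the unfolded protein response were lower with TAC in shUhrf1. The unfolded protein response list had 3 members that fell and 1 that rose of 16 (median -0.19, adjusted p = 0.0257, and 0.279 with an estimated correlation): Pdia4 fell by 0.88 ± 0.15, the chaperone calreticulin, Calr, by 1.26 ± 0.30 and Sdf2l1 at least 1.68-fold, and Asns rose by 0.61 ± 0.14. Of the adult contractile and calcium list 2 of 21 fell, Kcnip2, a subunit of the transient outward potassium channel, by 1.19 ± 0.25 and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, by 0.70 ± 0.16 (median -0.22, adjusted p = 0.0101, and 0.279 with an estimated correlation). Of 26 fatty acid oxidation genes Etfb alone fell, by 0.63 ± 0.14 (median -0.29, adjusted p = 8.49e-05, and 0.354 with an estimated correlation). No oxidative phosphorylation gene of 22 passed (median -0.10, adjusted p = 0.0478, and 0.408 with an estimated correlation). With median scaling the medians of the fatty acid oxidation, oxidative phosphorylation and unfolded protein response lists turned to 0.13, 0.082 and 0.30. With probes detected on all 12 arrays, 6 of the 12 list calls with TAC in shUhrf1 ended.

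The 10 largest rises in shUhrf1 were those of Serpina3n, Mfap5, Col3a1, Comp, Lox, Timp1, Col8a1, Col1a2, Col16a1 and Mfap4, and Comp, a cartilage matrix protein, rose at least 6.13-fold. The largest falls were those of Ano10 (-1.80 ± 0.28) and Pigh (-1.53 ± 0.20). Mhrt, a long noncoding RNA of the myosin heavy chain locus, fell by 1.46 ± 0.31, and Phkg1, Calr, Ky, Thrsp, Kcnip2, Cmtm8 and Itgb6 lay between -1.31 and -1.15. In all, 485 genes changed, 346 higher and 139 lower. This count was 2018 with median scaling, 2005 higher and 13 lower, where the median of all genes came to 0.45. The count fell with no filter on dim probes and with only the 2 groups compared, as given below under the processing. It was 113 without TAC shUhrf1 array 3, 151 without TAC shUhrf1 array 1, and 313, 117 and 260 without sham shUhrf1 array 1, 2 and 3.

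Set side by side, 343 genes changed in the same direction in both TAC comparisons and 0 in opposite directions, where independent lists would share 50.0. Over the 1796 genes that changed in either, the slope through the origin of the shUhrf1 response on the shControl response was 0.53. Over the genes that changed in shControl it was 0.51, and the slope of shControl on shUhrf1 over the genes that changed in shUhrf1 was 0.95. Genes chosen in one comparison have inflated changes there, which lowers a slope over genes chosen on its horizontal axis. When the shRNA labels were exchanged within each surgery, the slope of 0.51 was the lowest of 100 arrangements (lowest of the others 0.547). For the slope over all genes, 0.508, and for the gap between the counts of changed genes, 2 of 100 arrangements were as extreme, the real one included. With median scaling the corresponding slope was 0.69 and 23 of 100 arrangements were as low, and the larger count of changed genes then lay in shUhrf1 (2018 against 1272). With the endothelial score as a covariate, chosen after the data were seen, the slope over genes that changed in either was 1.06, and 613 genes changed in shUhrf1 against 7 in shControl. That score follows the groups, so the covariate also takes away what goes with TAC in shControl.

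**Figure D2:**
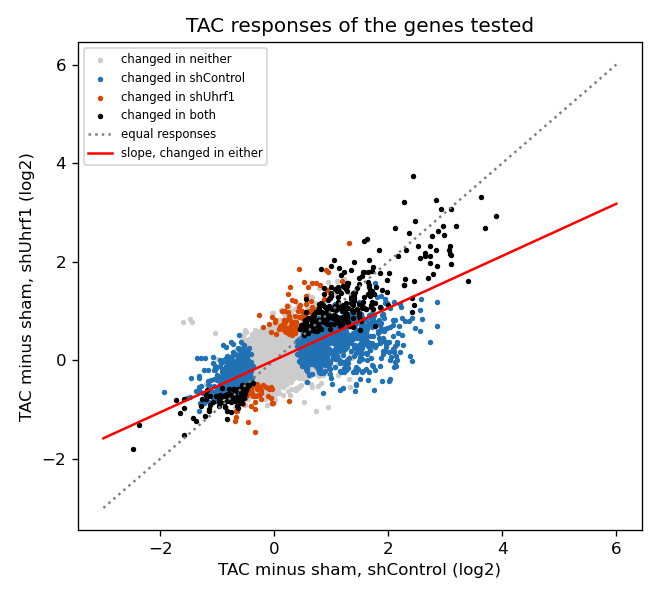
Log2 fold change with TAC in shUhrf1 cells (vertical axis) against that in shControl cells (horizontal axis), 1 point per gene, coloured by the comparison in which it changed; the dotted line marks equal responses and the red line the slope over genes that changed in either. Genes that changed in both comparisons number 343, all in the same direction, and the slope is 0.53 (0.78 with median scaling and 1.06 with the endothelial score as a covariate).

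The effect of the Uhrf1 hairpin without pressure overload was read from the sham arrays. In shUhrf1 4 genes rose and 0 fell. ND4L, a mitochondrially encoded subunit of complex I, was higher by 1.84 ± 0.18 (SE, adjusted p = 0.00209) and Mxi1, an antagonist of Myc, by 1.47 ± 0.22 (adjusted p = 0.0483). Asns, asparagine synthetase, was at least 1.37-fold higher and Lmod2, an actin-nucleating protein of cardiac thin filaments, at least 1.44-fold higher, each with adjusted p = 0.017. The next smallest p-values, of the immediate early gene Fosb (1.36 ± 0.24) and the heme transporter Slc48a1 (-0.82 ± 0.14), did not pass (adjusted p = 0.0724 each), and no preset heart gene did.

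Among the gene lists in sham cells, adult contractile genes were higher in shUhrf1 (median 0.21, adjusted p = 0.00198, and 0.512 with an estimated correlation), with 3 of 21 members past the test when adjusted over the list alone. Circadian clock genes (median 0.35, adjusted p = 0.0198, and 0.512 with an estimated correlation) and immediate early genes, which respond to cell isolation (median 0.29, adjusted p = 0.012, and 0.553 with an estimated correlation), were also higher. Macrophage markers (median -0.41, adjusted p = 0.0198, and 0.935 with an estimated correlation) and ribosomal proteins (median -0.17, adjusted p = 0.043, and 0.732 with an estimated correlation) were lower. No member of these 5 lists passed over all genes, and the macrophage median was 0.051 without sham shUhrf1 array 2, where no list was called lower. The 5 calls came to 1 without sham shControl array 1, 3 without sham shControl array 2, 2 with array weights and 3 with probes detected on all 12 arrays. At an unadjusted p under 0.05 limma gave 1154 genes where chance gives 437.3, and the count of 4 came to 24 in the authors' value table, 23 with an intensity trend and robust prior, and 57 with array weights, and to 1 or 2 without any of the 6 sham arrays. No gene passed with only the 2 groups compared. The count also fell with quantile normalization without background correction and with probes detected on all 12 arrays.

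Under pressure overload, cell cycle genes were lower in shUhrf1 than in shControl cells. All 16 measured members had negative differences and 7 fell (10 when adjusted over the list alone), with a median of -0.88 (bootstrap 95% interval -1.29 to -0.28). Cdc20 fell by 1.60 ± 0.18 (adjusted p = 0.00481), Mcm5 by 1.44 ± 0.20 and Ccnd1, cyclin D1, by 1.36 ± 0.26, and Top2a was at least 2.07-fold lower. The list test gave adjusted p = 7.23e-11, and 0.306 with an estimated correlation. Prc1, outside the list, fell by 1.95 ± 0.32.

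Endothelial markers were lower in the same comparison: all 12 had negative differences, 3 fell over all genes and 11 when adjusted over the list alone (median -1.39, interval -1.55 to -1.06, adjusted p = 1.53e-09, and 0.53 with an estimated correlation). Cldn5 fell by 1.61 ± 0.25, Cdh5 by 1.62 ± 0.32 and the receptor kinase Tie1 by 1.13 ± 0.25. Pcdh12 and Icam2, adhesion proteins of endothelial cells that stand outside the list, fell by 1.88 ± 0.37 and 1.78 ± 0.31. Macrophage markers did not move with them (median -0.03, interval -0.24 to 0.19, adjusted p = 0.707).

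Also lower were interferon response genes (median -0.61, adjusted p = 2.82e-05, and 0.591 with an estimated correlation; Isg15 fell by 1.18 ± 0.27), extracellular matrix (median -0.56, adjusted p = 0.00155, and 0.591 with an estimated correlation; Col4a2 fell by 0.88 ± 0.21) and fibroblast markers (median -0.39, adjusted p = 0.00565, and 0.591 with an estimated correlation; Col6a2 fell by 0.98 ± 0.23). Smooth muscle and pericyte markers had a median of -0.52 (adjusted p = 0.0289, and 0.53 with an estimated correlation) and ribosomal proteins of -0.20 (adjusted p = 0.0357, and 0.591 with an estimated correlation), with no member past the test. The median of the ribosomal list turned to 0.14 with median scaling. With the endothelial score as a covariate, chosen after the data were seen, the interferon, matrix and fibroblast medians turned to 0.20, 0.17 and 0.60, and the cell cycle median was -0.50.

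The largest falls with shUhrf1 after TAC were those of 5 probes named for replication-dependent H2A histones, H2ac15 (-2.56 ± 0.41), H2ac22, H2ac12, H2ac7 and H2ac24 (-2.23 to -2.04). These genes are nearly identical in sequence, so which of them changed is uncertain. Spon2, a matrix protein, fell by 1.94 ± 0.48 and the actin-binding protein Tagln2 by 1.78 ± 0.37. Higher in shUhrf1 were ND6 (1.82 ± 0.34) and ND4L (1.48 ± 0.18), both mitochondrially encoded subunits of complex I. They were followed by Ppip5k2 (1.46 ± 0.26), Ktn1, Nkiras1, Nampt, the enzyme of NAD salvage (1.34 ± 0.26), the complex I subunit Ndufb4 (1.33 ± 0.26), Morf4l1b, Zc3h6 and Vbp1. Of the preset heart genes none passed: Nppa differed by 0.02 ± 0.29, Nppb by -0.61 ± 0.20 (adjusted p = 0.112), Myh7 by 1.01 ± 0.52 and Col1a1 by -0.62 ± 0.28 (adjusted p = 0.25).

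In all, 253 genes changed with shUhrf1 after TAC, 134 higher and 119 lower (257 and 45 with median scaling, where the median of all genes came to 0.28, and 140 and 248 with scaling to the median of detected probes, chosen after the data were seen). The count was 9 without TAC shControl array 2, 41 without TAC shControl array 3, 35 without TAC shUhrf1 array 2, 11 without TAC shUhrf1 array 3, 159 without sham shControl array 3 and 383 without sham shUhrf1 array 2, and 0 with the endothelial score as a covariate. It also fell with no filter on dim probes and rose with an intensity trend and robust prior, as given below under the processing. Of the 134 higher genes 122 had the same sign in sham cells, and of the 119 lower genes 54. Together these were 176 of 253, and 6 of 20 arrangements of the sham arrays gave as many (one-sided exact permutation p = 0.3). ND4L, Mxi1 and Lmod2 passed in both surgeries.

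**Figure D3:**
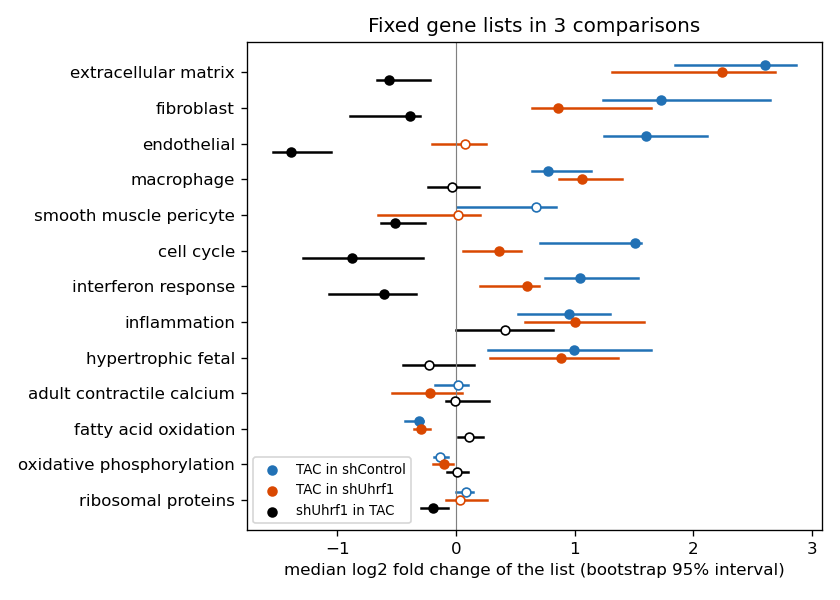
Median log2 fold change of selected gene lists with TAC in shControl (blue), with TAC in shUhrf1 (orange) and with shUhrf1 after TAC (black), with bars for the bootstrap 95% interval, filled points where the list test passed at the preset correlation of 0.01 and open points where it did not. With an estimated correlation 0 lists pass in each comparison. Cell cycle and endothelial lists are higher with TAC in shControl (1.5 and 1.60) and lower with shUhrf1 after TAC (-0.88 and -1.39). With genes below background at their bound the cell cycle median with TAC is 0.72 in shControl and 0.25 in shUhrf1.

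Genes that TAC changed in shControl and shUhrf1 changed in the opposite direction after TAC numbered 129. Of these, 103 rose with TAC and were lower with shUhrf1, among them Cdc20, Mcm5, Top2a, Cldn5, Cdh5 and Prc1, and 26 fell and were higher. Another 4 genes rose in both, and independent lists would give 23.6 opposite genes. Both comparisons use the TAC shControl arrays with opposite sign, which alone makes changes oppose: the correlation across genes was -0.53 against -0.50 in simulated groups without any effect. Simulated groups gave 0 opposite genes that passed. Among equally many genes of smallest p in the simulated groups 132.8 ± 8.5 had opposite signs (mean ± SD of 100 simulations), against the 129 observed. The simulated correlation and these signs follow from the shared arrays by construction, so they do not say how many of the 129 do. The covariance was -0.109 against -0.0206 ± 0.0006 simulated (SD), which argues against noise as simulated being the whole source. The groups of 3 arrays were not split. A deviation common to the TAC shControl arrays therefore stays open for part or all of the excess over independent lists. The count of 129 fell to 78 and 73 without sham shControl array 2 and 3, to 4 and 20 without TAC shControl array 2 and 3, to 15 and 7 without TAC shUhrf1 array 2 and 3, to 51 with median scaling, to 26 with no filter on dim probes and to 77 with probes detected on all 12 arrays, and it was 229 without sham shUhrf1 array 2. Among the settings chosen after the data were seen, it was 210 with scaling to the median of detected probes and 0 with the endothelial score as a covariate.

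Whether the TAC response itself differed between shUhrf1 and shControl was tested as an interaction. No gene passed over all genes by limma, where 866 had an unadjusted p under 0.05 against 437.3 by chance and the smallest adjusted p was 0.162. The smallest p-values, none passing, were those of Cdc20, the transcriptional repressor Bcl6b, the formin Fhod1 (-1.27 ± 0.22), Col6a2, Ift122 (-1.81 ± 0.33) and Dgcr8. Cdc20, Bcl6b, Col6a2 and Dgcr8 were undetected on every array of at least 1 group, so no size is given for them. Without sham shUhrf1 array 2, which had the lowest endothelial score, 102 genes passed, and 29 passed without TAC shControl array 1.

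By list, endothelial markers responded less to TAC in shUhrf1 by -1.55 (adjusted p = 8.83e-11, and 0.422 with an estimated correlation), with 11 of 12 members lower when adjusted over the list alone. Cell cycle genes had a median of -0.82 (adjusted p = 3.33e-11, and 0.284 with an estimated correlation), with 7 of 16 lower over the list alone. Of the 16, 12 were undetected on every array of at least 1 group, so the size of that median is uncertain. Over the 4 members detected in every group, a choice made after the data were seen, the cell cycle median was -0.27. Genes silent in sham cells drop out of that value by construction. Over such members the endothelial, fibroblast and matrix medians were -1.66, -0.83 and -0.51. Fibroblast markers (-0.83, adjusted p = 0.000274, and 0.547 with an estimated correlation), interferon response genes (-0.54, adjusted p = 0.00198, and 0.767 with an estimated correlation), smooth muscle and pericyte markers (-0.63, adjusted p = 0.014, and 0.422 with an estimated correlation) and the extracellular matrix (-0.26, adjusted p = 0.00811, and 0.83 with an estimated correlation) followed. With the endothelial score as a covariate, chosen after the data were seen, the fibroblast, interferon and matrix medians of the interaction turned to 0.59, 0.38 and 0.20, and the cell cycle median was -0.38. Adult contractile genes had a median of -0.20 (adjusted p = 0.014, and 0.5 with an estimated correlation), which turned to 0.13 with median scaling. Hypertrophy genes were not among the lists that passed, with Nppa at -0.35 ± 0.41, Nppb at 0.03 ± 0.28 and Myh7 at 0.22 ± 0.74.

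**Figure D4:**
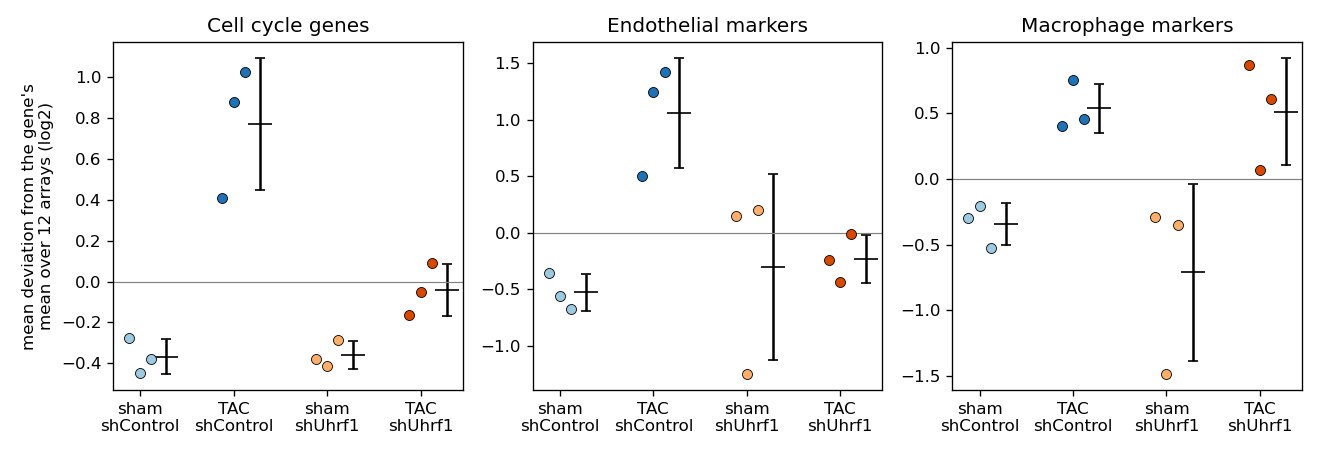
Mean deviation of cell cycle genes, endothelial markers and macrophage markers from each gene's mean over the 12 arrays (log2, 1 point per array, black bars for the mean ± SD of 3 arrays). The endothelial scores of the 3 TAC shControl arrays, 0.51, 1.24 and 1.43, lie above those of the 3 TAC shUhrf1 arrays, -0.24, -0.44 and -0.01, and sham shUhrf1 array 2 stands apart at -1.25.

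The lists of DNA methylation machinery, glycolysis, autophagy, p53 and atrial markers had no call with TAC in shControl or with shUhrf1 after TAC, and imprinted genes had none with shUhrf1 after TAC. With shUhrf1 after TAC the medians were 0.00 for the DNA methylation machinery, -0.02 for glycolysis and glucose uptake, 0.09 for autophagy and atrophy, 0.12 for p53 and apoptosis, 0.54 for atrial markers and -0.31 for imprinted genes. The list of germline genes silenced by methylation and the erythrocyte list had 2 measured members each and were not tested. Their medians were -0.14 and 1.23, and the erythrocyte median with TAC in shControl was -1.33. Of the adipocyte and lymphocyte markers 0 were measured, and Dnmt3a was not detected on enough arrays to be tested.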

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

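The tests of the spread between arrays, of endothelial cells and of a batch, and the relabelling under other scalings, were chosen only after the results were seen. For 7 gene lists the TAC response differed between shUhrf1 and shControl by the test of the interaction, with lower medians in shUhrf1. The medians of the difference were -1.55 for endothelial markers, -0.82 for cell cycle genes, -0.83 for fibroblast markers, -0.54 for interferon response genes, -0.63 for smooth muscle and pericyte markers, -0.26 for the extracellular matrix and -0.20 for adult contractile genes. None of these differences passed with an estimated correlation, and with the endothelial score as a covariate the fibroblast, interferon and matrix medians turned to 0.59, 0.38 and 0.20.

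The first pattern is that cell cycle genes were lower in TAC shUhrf1 than in TAC shControl, with a median of -0.88. A smaller share of all non-myocytes in the TAC shUhrf1 preparations would lower their markers alike. Macrophage markers lay 1.36 above endothelial markers and their intervals did not overlap, so these markers did not fall alike. Those intervals are drawn over genes, not arrays, so they cannot decide about the preparations. Fibroblast and smooth muscle and pericyte markers were also lower (medians -0.39 and -0.52), so a smaller share of some non-myocytes stays open. A single TAC array is argued against, as the median nearest 0 among the 6 fits without a TAC array was -0.70. More endothelial cells in the TAC shControl preparations may contribute: with the endothelial score as a covariate the median was -0.50 (interval -0.82 to -0.24) against -0.88, so 0.565 of it remained, and these cells and the knockdown cannot be told apart because the score follows the groups. Knockdown of Uhrf1 in the myocytes stays open, since the sham median of -0.019 decides nothing where 4 of 16 cell cycle genes were detected on 3 or more sham arrays.

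The second pattern is that fewer genes changed with TAC in shUhrf1 (485) than in shControl (1654). For a larger spread between shUhrf1 arrays, the ratio of median residual SDs was 0.977, so the typical probe did not spread more. The ratio does not test the counts, which came from 1 fit with a shared spread. A median over probes can also miss spread in some genes: the endothelial score was -1.25 on sham shUhrf1 array 2, against 0.15 and 0.20 on arrays 1 and 3. A smaller TAC response in shUhrf1 may account for it: the slope over genes that changed in shControl, 0.51, was reached by 1 of 100 arrangements of the shRNA labels, the real one (lowest other 0.547), and over all genes 2 of 100 were as low. It stays open, because with median scaling the slope was 0.69 and 23 of 100 arrangements were as low (0.48 and 1 of 100 with scaling to detected probes). With the endothelial score as a covariate 7 genes changed in shControl and 613 in shUhrf1, and the slope over genes that changed in either was 1.06 against 0.53, but that score follows the groups.

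Other splits of the arrays were set beside each count. The 3 against 3 arrays of a comparison make 10 splits, too few for a share under 0.05. The real split gave 1654, 485, 4 and 253 genes for TAC in shControl, TAC in shUhrf1, shUhrf1 in sham and shUhrf1 in TAC, each reached by 1 split, and the highest other split gave 0. Every other split mixes arrays of both groups, so a real difference between them widens the spread and lowers the count by construction. The counts of 0 therefore say little about chance. For the interaction the real count is 0, so 100 of 100 splits gave as many by construction, which says nothing about chance. The highest of the others gave 383 genes, and 4 of the 100 gave any gene. Which labels were exchanged in the arrangement with 383 genes is not given here. An arrangement that exchanges the shRNA labels of TAC alone sums the shRNA differences of both surgeries, so a high count need not come from chance.

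Differences with shUhrf1 after TAC had the same sign in sham for 122 of 134 higher and 54 of 119 lower genes, and 6 of 20 arrangements of the sham arrays gave as many in all (one-sided exact permutation p = 0.3). The second principal component parted all shControl from all shUhrf1 arrays. shUhrf1 arrays had 641.7 more detected probes after sham surgery and 742.7 more after TAC, each above the largest SD within a group of that surgery (374 and 590). Ribosomal proteins were lower with shUhrf1 in both surgeries (medians -0.17 and -0.20), though neither call held with an estimated correlation and the second median turned with median scaling. A batch of arrays or preparations that follows the shRNA cannot be told apart from the hairpin, since slides are not named.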

How the results depend on the processing

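The endothelial score covariate and the scaling to the median of detected probes were chosen only after the results were seen. Directions of called lists and genes held in every alternative except those given here, and calls that ended are given as counts in the last paragraph. What limits these arrays is signal over background: between 27.2% and 32.9% of probes were detected per array, so the median of an array lies at a probe below background. The slide as a block was not run, because slides are not named, and Uhrf1 has no value among probes detected on all 12 arrays.

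Median scaling gave 2018 genes for TAC in shUhrf1, a slope of 0.78 and 51 genes changed in opposite directions. It turned the medians of 7 lists: adult contractile genes with TAC in shControl (-0.072) and in the interaction (0.13), ribosomal proteins with shUhrf1 in TAC (0.14), and circadian clock (0.23), fatty acid oxidation (0.13), oxidative phosphorylation (0.082) and unfolded protein response genes (0.30) with TAC in shUhrf1. By its construction it moved the median of all genes, at most to 0.45 for TAC in shUhrf1, against 0.01 in the main fit. Scaling to the median of detected probes gave 1 gene for shUhrf1 in sham, 388 for shUhrf1 in TAC and 210 in opposite directions, and turned adult contractile genes with TAC in shControl (-0.35) and cell cycle genes with TAC in shUhrf1 (-0.015). The cause was not tested.

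The endothelial covariate gave 7 genes for TAC in shControl, 613 for TAC in shUhrf1, 0 for shUhrf1 in TAC, 4 lists for TAC in shControl, a Uhrf1 difference of -0.81 (adjusted p = 0.521), a slope of 1.06 and 0 genes in opposite directions. By its construction it removes what follows the score, and the score follows the groups; the score is the mean of the endothelial markers themselves, so their own values under it carry no information. It turned, with TAC in shControl, imprinted genes (-0.083), endothelial markers (-0.12), macrophage markers (-0.35), Dcn (-0.27) and Laptm5 (-0.12). With shUhrf1 in TAC it turned the extracellular matrix (0.17), interferon response (0.20), endothelial (0.083), fibroblast (0.60) and macrophage lists (0.86), and in the interaction the extracellular matrix (0.20), interferon response (0.38), endothelial (0.25) and fibroblast lists (0.59).

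The Uhrf1 difference was -0.33 in the authors' value table (adjusted p = 0.0509), and -1.35 with no filter on dim probes (0.112) and with only the 2 groups compared (0.0676), against 0.0355. The authors' table gave 24 genes for shUhrf1 in sham. No filter gave 238 genes for TAC in shUhrf1, 55 for shUhrf1 in TAC, 1 for the interaction and 26 in opposite directions, since more probes were tested. Only the 2 groups compared gave 306 for TAC in shUhrf1 and 0 for shUhrf1 in sham, with fewer arrays in the fit. Probes detected on all 12 arrays gave 1 gene for shUhrf1 in sham, 77 in opposite directions, 6 lists for TAC in shUhrf1 and 3 for shUhrf1 in sham, with fewer genes tested. Quantile normalization without background correction gave 1 gene for shUhrf1 in sham and a Uhrf1 difference of -0.60 (adjusted p = 0.0300). The intensity trend gave 23 for shUhrf1 in sham and 388 for shUhrf1 in TAC, and array weights 57 for shUhrf1 in sham and 2 lists there. The estimated correlation left 0 lists in each comparison. Where no construction is named, the cause was not tested.

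Leaving out each array in turn gave 875 to 1684 genes for TAC in shControl, 113 to 511 for TAC in shUhrf1, 1 to 4 for shUhrf1 in sham, 9 to 383 for shUhrf1 in TAC and 0 to 102 for the interaction. The lists called numbered 9 to 11, 9 to 13, 1 to 6, 3 to 8 and 5 to 9 in that order. The Uhrf1 difference was -1.71 to -1.01, the slope 0.38 to 0.61, and genes in opposite directions 4 to 229. The hypertrophic list of the interaction ranged from -0.17, without sham shControl array 2, to 0.074. Without sham shUhrf1 array 2 endothelial markers with TAC in shUhrf1 came to -0.44 (range to 0.39), and macrophage markers with shUhrf1 in sham to 0.051 (range from -0.66). The arrays that move a count by over 1.5 times are named beside the counts of genes. For lists, 1 and 3 passed for shUhrf1 in sham without sham shControl array 1 and 2, and 3 passed for shUhrf1 in TAC without TAC shControl array 3 or TAC shUhrf1 array 2.

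With the replicate number as a block, 1603, 478, 3, 215 and 0 genes changed in the 5 comparisons and 109 in opposite directions, and Uhrf1 kept its call (adjusted p = 0.0401). The block moved no count by over 1.5 times, ended 1 call of a list, and ended 10 and added 6 calls of named genes. Equal numbers did not pair the arrays: their correlations ran from -0.157 to 0.254, 4 of 18 lay over 0.1, and 3 of 12 arrays correlated best with their own number. Of 41 list calls the estimated correlation ended 41, the filter for all arrays 12, the endothelial covariate 7, the authors' table and array weights 4 each, the mean of a gene's probes and scaling to detected probes 3 each, median scaling 2, quantile normalization without background correction 1, and no filter and the intensity trend 0 each. Only the 2 groups compared ended 3 of 34. Of 180 calls of named genes the endothelial covariate ended 113, no filter 65, only the 2 groups compared 32, the authors' values 28, median scaling 27, array weights 12, the intensity trend and scaling to detected probes 10 each, and quantile normalization without background correction 8. The filter for all arrays ended 0 of 108. Over the 12 fits without an array, 53 of 492 list calls and 375 of 2160 calls of named genes ended. All these counts leave out values that turned, whether or not a call ended with them. Turned list medians numbered 12 with the endothelial covariate, 7 with median scaling, 2 with scaling to detected probes and 3 over the fits without an array. Of the named genes 2 turned with the endothelial covariate.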

Other observations

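The test of Uhrf1 among cell cycle genes and the choice of mitochondrial genes were made only after the results were seen. Genes encoded in the mitochondrial genome did not move together with the Uhrf1 hairpin. ND4L was higher with shUhrf1 in sham cells by 1.84 ± 0.18 (adjusted p = 0.00209) and after TAC by 1.48 ± 0.18 (adjusted p = 0.00481). ND6, the subunit encoded on the opposite strand from the others, was higher by 1.82 ± 0.34 after TAC (adjusted p = 0.0198) and differed by 1.61 ± 0.34 in sham cells, which did not pass (adjusted p = 0.0981). ND4, which lies on the same transcript as ND4L, differed by 0.21 and -0.15, and ATP6, COX2, CYTB, ND1 and ND5 did not pass in either surgery.

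Nuclear genes of other groups also rose singly with shUhrf1 after TAC while their lists did not pass. Hspa5, the main chaperone of the endoplasmic reticulum, rose by 1.17 ± 0.18 (adjusted p = 0.012), and its list had a median of 0.15. Atp5a1, a subunit of the ATP synthase, rose by 1.07 ± 0.19 and Sdhd, a subunit of complex II, by 0.86 ± 0.18, and the oxidative phosphorylation list had a median of 0.01. Lmod2 rose by 1.19 ± 0.14 and Mxi1 by 1.17 ± 0.22, in the direction they had in sham cells.

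One hypothesis concerns the lower Uhrf1 signal in TAC shUhrf1 cells. Uhrf1 is itself expressed in cycling cells, so fewer cycling cells in the TAC shUhrf1 preparations could lower it without any action of the hairpin. If so, its difference of -1.35 should lie within those of the cell cycle genes that rose with TAC in shControl, and it did: the 11 genes ranged from -1.60 to -0.08, and 3 of them fell more than Uhrf1. The hairpin itself predicts a lower Uhrf1 as well, so this value does not separate them.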
